A study of Aspergillus oryzae RIB40 with 2 samples.

How the data were processed

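Genomic DNA from mycelium grown for 3 days at 30 °C was sheared to about 500 bp, and 1 µg was labelled with Cy3 (wild type RIB40) or Cy5 (strain), per the labels' protocols. Each of the 2 strains has 1 array, on a custom array of 60-mer probes. Per the file headers, both arrays are of 1 design, and the submitters' processing notes name Agilent Feature Extraction 9.5.1. The deposited files of both arrays hold scanner intensity of spot and local background per channel. The processed intensity of each channel is, per the file headers, the signal after subtraction of a fitted spatial background surface and scaling by 1 linear dye factor, written to 3 significant digits. The deposited log10 ratio column is red over green processed signal and equalled the log10 ratio of the processed signals within 0.004, and the deposited series table holds log2 ratios that equalled log2 of red over green processed signal within 5e-07 for its 24196 features, with a median of 0 on both arrays. The genome build of the array is not given in the sources used here.

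Each array has 43647 spots, of which 24201 carry a gene name and a probe sequence. Spots with an outlier flag were left out, 11 in Ao-210k-dup and 29 in Ao-700k-dup. None was saturated, and none failed to be well above background in either channel. Log2 of red over green processed signal was centred on the array median over the remaining spots, with no loess or quantile step, and the spots of a gene were averaged. Gene names were matched by locus tag to an annotation of assembly ASM18445v3, where 12009 of 12100 (99.2%) had a row and 11997 were on the 8 chromosomes. The annotation was used for symbols, for gene order and for lengths in kb, and no coordinates are given because the array's build is unknown. The file descriptions carry almost no products, so the fixed gene lists were matched on symbols after the files were opened, the transposon list matched no gene, and lists under 3 members have values and no percentile.

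Segments were called per chromosome by penalised least squares (optimal partitioning) on values winsorised at 3 robust SD around a running median of 11 genes, with penalty 6 × noise variance × log n, at least 10 genes per segment, and a call where the segment median was at least 0.3 from the centre. The target is the largest called gain on the labelled chromosome. Windows of the labelled size (210 or 700 kb) were slid over every chromosome and needed at least 10 genes and, at a chromosome end, 90% of that size. Genes are counted beyond 0.5. List medians were compared with 10000 random lists of the same size. Genes were named by a rule fixed before the data were examined: the 2 nearest genes at each side of a boundary, up to 10 genes with a symbol or an informative product in each segment, the 5 highest and 5 lowest genes outside it, up to 5 shared by both arrays, members of the selection list, and members of the starch, protease and secondary metabolism lists in a segment. Within segments, the rule put the number of probes before position, but only symbols and position were used. No p-value was computed because each strain has 1 array.

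The segmentation was tested on simulated data in 20 simulations per case. Each of 11997 genes drew a value at random, with replacement, from the real values outside the called segments. Such draws hold no regional rises, so the test does not cover false calls or boundaries in their presence. Implanted gains of log2 1 with the target's number of genes (74 and 215) were recovered within 2 genes in all 20 simulations on both arrays, as were gains of 0.6 with 40 genes. Gains of 0.3 with 40 genes were recovered in 6 of 20 for Ao-210k-dup and 7 of 20 for Ao-700k-dup. This implanted size equals the call threshold of 0.3 on the segment median, so the cut-off itself limits the rate. In that case 1 and 3 called segments matched no implanted gain within 2 genes, against 0 in the other cases.

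Alternatives were normexp background correction (offset 50), the series table's values, leaving out dim probes, subtraction of a GC trend, intensity loess, the difference between the arrays, centring outside the labelled chromosome, the mean, penalties of 3 and 12, minimum sizes of 3 and 20 genes, a hidden Markov model with 3 states, call thresholds of 0.2 and 0.5 and gene thresholds of 0.3 and 0.7. The GC trend was a lowess over the medians of GC levels with at least 20 genes, because most probes share 1 GC level. Each spot of a probe alone, and loess and the GC trend for the gene lists, were added after the data were seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and hmmlearn 0.3.3, and R 4.3.3 with limma 3.58.1.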

Results

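Array comparative genomic hybridisation was used to compare the gene dosage of 2 strains of the filamentous fungus Aspergillus oryzae with that of their wild-type parent, RIB40. Per the labels, strain Ao-210k-dup carries a tandem duplication of about 210 kb on chromosome 8 and strain Ao-700k-dup a tandem duplication of about 700 kb on chromosome 2, and the comparison was made to check for these duplications. Each strain was hybridised on 1 array, with strain DNA labelled with Cy5 and wild-type DNA with Cy3. Values are log2 ratios of strain over wild type centred on the array median, so that a doubled segment of a haploid genome has a value of 1. The arrays gave values for 12099 genes in Ao-210k-dup and 12100 in Ao-700k-dup, nearly all from 1 probe printed as 2 spots. The 2 spots of a probe correlated across genes at r = 0.976 in Ao-210k-dup and 0.977 in Ao-700k-dup, and the SD of a spot around its pair was 0.034 in both. With 1 array per strain there was no biological replicate, so all values below are descriptions of these 2 hybridisations, no test was made, and the number of arrays limits the precision. Interquartile ranges are over genes, which are not replicates.

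Both strains are labelled as deleted for pyrG, which encodes orotidine 5'-phosphate decarboxylase and serves as a uridine selection marker, and as carrying truncated pyrG pieces at the 2 ends of the duplicated region. The pyrG probe (AO090011000868, chromosome 7) was above wild type on both arrays, with a log2 ratio of 0.93 in Ao-210k-dup and 0.97 in Ao-700k-dup. These became 1.70 and 1.77 with normexp background correction. Where the probe lies within the gene relative to the deleted part is not given in the sources used here, so the value does not check the deletion itself. Of the neighbouring genes, AO090011000867 read 1.43 in Ao-210k-dup and 2.17 in Ao-700k-dup, and AO090011000869 read 0.85 and 0.32. AO090011000866 was below wild type on both arrays, at -0.72 and -0.79, while AO090011000865 read -0.13 and -0.08 and AO090011000870 read -0.14 and -0.09. The gain at AO090011000867 was smaller with normexp, at 0.30 in Ao-210k-dup and 0.76 in Ao-700k-dup, and in Ao-700k-dup it rested on 1 spot because the other carried an outlier flag. AO090011000865, AO090011000869 and AO090011000870 were chosen after their values were seen.

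In Ao-210k-dup, a run of 74 genes on chromosome 8 stood near a doubled dosage. The median log2 ratio was 0.91 (interquartile range 0.81 to 1.06), which is 1.87 times wild type, and the same genes had a median of -0.04 (interquartile range -0.13 to 0.08) on the Ao-700k-dup array. All 74 genes were above 0.5, the lowest at 0.61 and the highest at 1.29, against 1.74% of the 12025 genes outside the segment and none of the 74 on the other array. None of 144 non-overlapping runs of 74 genes on the other chromosomes reached this median, the highest being 0.29. On gene order, the gain began at AO090103000159 (0.88) and AO090103000158 (1.11) and ended with AO090103000074 (1.29) and AO090103000073 (1.15). The nearest genes outside it were AO090103000161 (-0.16) and AO090103000160 (-0.11) at one side and AO090103000072 (-0.23) and AO090103000070 (0.01) at the other. The labels name the ends H71 and H160, without saying what these markers are. Inside the segment, 2 genes had a symbol: bxlB, a beta-xylosidase gene (AO090103000120), at 1.06, and abfI (AO090103000088) at 0.85.

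The segment of Ao-210k-dup spanned 214 kb between the midpoints of its boundary gaps, with limits of 213 and 215 kb, measured on assembly ASM18445v3. The build used to design the array is not given in the sources used here. The best window of the labelled 210 kb on chromosome 8 had a median of 0.91 over 73 genes, all of them in the segment, and the same window had -0.03 on the other array. The best windows of that size on the other 7 chromosomes had medians from 0.34 on chromosome 2 to 0.48 on chromosome 5. With normexp, the segment median was 1.44, with 62 of the 74 genes higher and 12 lower, and 68 remained above 0.5. AO090103000158 then read 1.97, bxlB 1.90 and abfI 0.86.

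In Ao-700k-dup, 215 genes on chromosome 2 formed a single gain. The median log2 ratio was 1.03 (interquartile range 0.91 to 1.15), or 2.04 times wild type, and the same genes had a median of 0.03 (interquartile range -0.09 to 0.15) on the Ao-210k-dup array. All 215 were above 0.5, with values from 0.63 to 1.51, against 0.42% of the 11885 genes outside the segment, and 1 of the 215 was above 0.5 on the other array. None of 44 non-overlapping runs of 215 genes on the other chromosomes came near it, the highest being 0.04. The gain ran from AO090003001003 (1.04) and AO090003001004 (1.21) to AO090003001256 (0.96) and AO090003001258 (1.13). Its outer neighbours were AO090003001000 (0.14) and AO090003001001 (-0.11) before it and AO090003001259 (-0.25) and AO090003001260 (-0.06) after it. The labels name the ends B1003 and B1258.

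The 10 genes with a symbol that come first in the Ao-700k-dup segment were named. gldB, a glycerol dehydrogenase gene, read 1.41, lys9, of lysine biosynthesis, 1.38, and kgd1, a subunit of 2-oxoglutarate dehydrogenase, 1.18. fbp1, encoding fructose-1,6-bisphosphatase, read 0.86 and sod2, encoding manganese superoxide dismutase, 1.07. The others were nar1 at 0.98, psf3 at 1.09, aarA at 1.19, prm1 at 1.01 and cdc31 at 1.13. On the Ao-210k-dup array these 10 genes ranged from -0.16 (fbp1) to 0.35 (gldB). With normexp the segment values spread, with 161 genes higher, 54 lower and 195 above 0.5. psf3 then read 0.50, gldB 2.42 and lys9 2.34. The segment spanned 698 kb on assembly ASM18445v3, with limits of 694 and 702 kb. The best window of the labelled 700 kb had a median of 1.03 over 215 genes, and on the other chromosomes the best such windows ranged from 0.02 on chromosome 8 to 0.07 on chromosome 1.

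**Figure D1:**
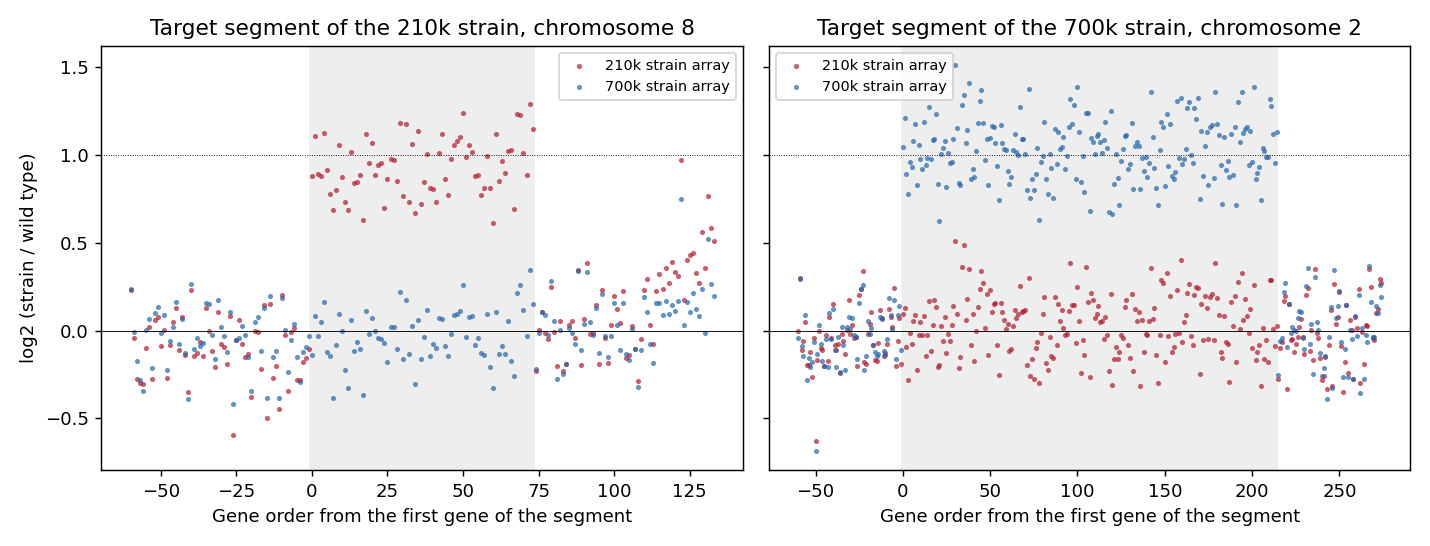
Log2 ratio of strain over wild type (vertical axis) for genes in order around each target segment (horizontal axis, counted from the first gene of the segment), on both arrays. Shading marks the 74 genes of the chromosome 8 segment and the 215 genes of the chromosome 2 segment, and the dotted line marks 1. In each segment the array of the labelled strain sits near 1 (medians 0.91 and 1.03) and the other near 0 (medians -0.04 and 0.03).

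Outside the target segment, 9 gains and no losses were called in Ao-210k-dup, and no segment was called in Ao-700k-dup. The highest was on chromosome 7, from AO090011000747 to AO090011000796, where 44 genes had a median of 0.64 (interquartile range 0.51 to 0.77) against -0.02 on the Ao-700k-dup array. It spanned 121 kb on assembly ASM18445v3 and is not named in the labels. A gain of 21 genes at the end of chromosome 1, from AO090005000006 to AO090308000022, had a median of 0.58 in Ao-210k-dup and 0.27 in Ao-700k-dup. The other 7 gains, on chromosomes 1, 2, 3, 4, 5 and 8, had medians between 0.31 and 0.45 in Ao-210k-dup and between 0.08 and 0.14 in Ao-700k-dup. The number of segments called outside the target in Ao-210k-dup was 2 at a call threshold of 0.5, 6 with normexp or at a penalty of 12, and 14 with a hidden Markov model. With the difference between the arrays it was 4 in both strains, mirrored by construction.

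**Figure D2:**
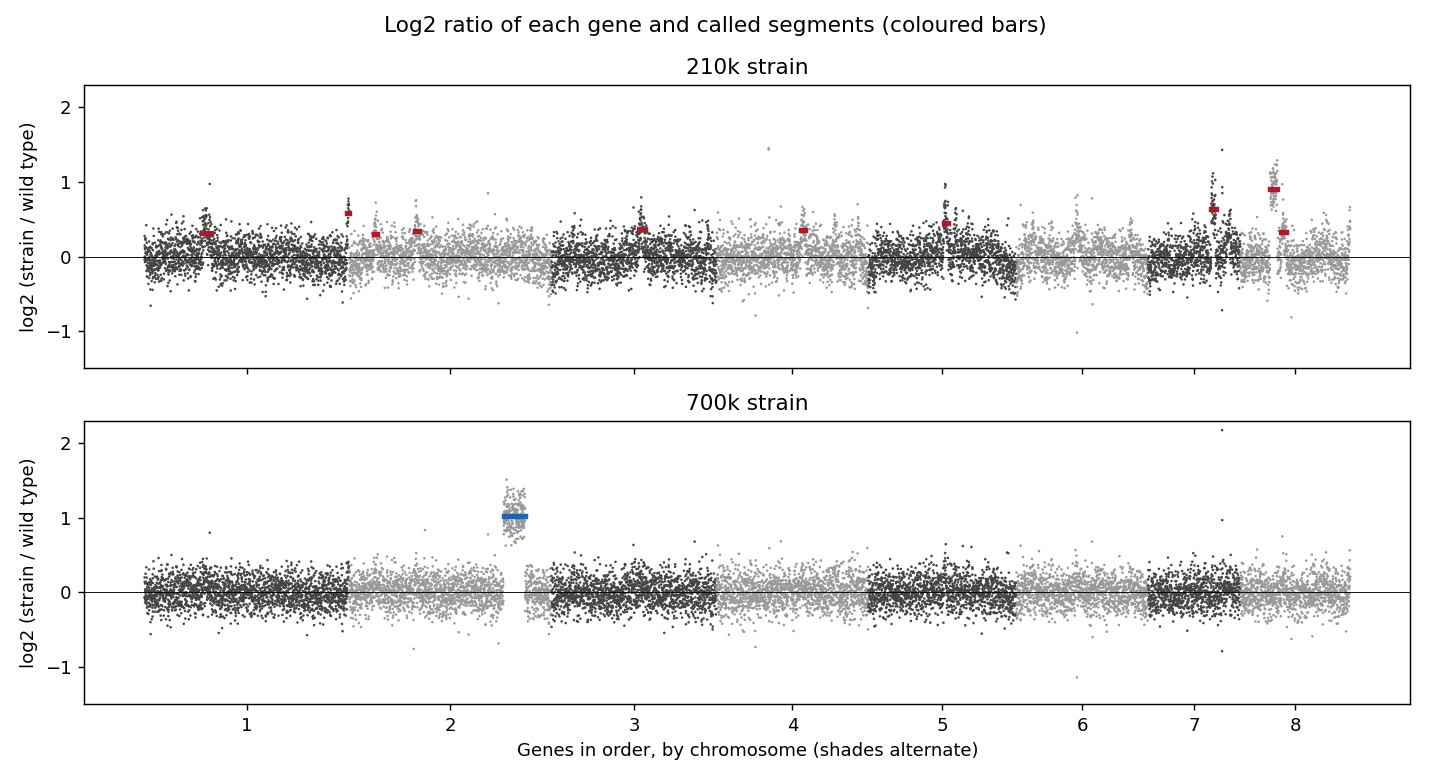
Log2 ratio of strain over wild type (vertical axis) of each gene in order along the 8 chromosomes (horizontal axis), for Ao-210k-dup (upper) and Ao-700k-dup (lower). Coloured bars are called segments at their medians: 10 in Ao-210k-dup, the highest at 0.91 on chromosome 8, and 1 in Ao-700k-dup, at 1.03 on chromosome 2.

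Beyond a log2 ratio of 0.5 in either direction, 243 genes outside the target were found in Ao-210k-dup, 209 higher and 34 lower, and 75 in Ao-700k-dup, 50 higher and 25 lower. Of the 209 higher in Ao-210k-dup, 122 lay in called segments and 22 were mitochondrial. The 2 arrays shared 37 higher and 16 lower genes, against 0.881 and 0.069 for independent lists over 11810 genes. The 37 include 9 mitochondrial genes, which belong to 1 genome and are not independent. Both arrays used the same wild-type reference and dye orientation, so part of this excess may come from these. The values of the 2 arrays are also correlated at r = 0.882 outside both targets, so independent lists are not a fitting reference and the excess is only a description. Across 11707 nuclear genes outside both targets the 2 arrays correlated at a Pearson r of 0.882 and a Spearman rho of 0.90, with genes not being independent replicates. By chromosome, r ranged from 0.756 to 0.917. With normexp the counts beyond 0.5 were 962 in Ao-210k-dup and 702 in Ao-700k-dup. Intensity loess gave 34 in Ao-700k-dup, and the difference between the arrays gave 75 in Ao-210k-dup.

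The highest genes outside the target in Ao-210k-dup were 3 mitochondrial genes, AO09M000000017 (1.61), AO09M000000010 (1.48) and AO09M000000016 (1.46), followed by AO090012000626 (1.45) and AO090012000627 (1.43). The last pair are neighbours on chromosome 4 and read -0.07 and -0.19 in Ao-700k-dup. niiA, the nitrite reductase gene beside them, read 0.11 and 0.12 on the 2 arrays. In Ao-700k-dup the highest were AO090011000867, pyrG, gb_TF279 (0.94, against -0.04 in Ao-210k-dup), AO09M000000017 (0.86) and thiA, of thiamine synthesis (0.83, against -0.23). gb_TF279 has no position in the annotation used, so it was counted outside the target without being placed and whether it lies inside the duplicated segment is unknown. The genes on either side of thiA, AO090003000089 and AO090003000091, read 0.01 and 0.05 in Ao-700k-dup. The lowest in Ao-210k-dup were AO090020000007 (-1.02), AO090010000698 (-0.82), AO090012000466 (-0.79), AO090011000866 (-0.72) and AO090166000122 (-0.69). In Ao-700k-dup they were AO090020000007 (-1.14), AO090011000866 (-0.79), AO090001000718 (-0.76), AO090012000466 (-0.73) and AO090003000945 (-0.69). The 2 spots of AO090001000718 disagreed, at -0.17 and -1.35. With normexp, AO090010000698 read -0.27 in Ao-210k-dup, AO090012000466 -0.43 on both arrays and AO090003000945 -0.26 in Ao-700k-dup, AO090011000866 read -0.39 and -0.41, and AO090020000007 read -0.62 and -0.71, while AO090012000627 read 2.47 in Ao-210k-dup. With intensity loess, AO09M000000017 read 1.19 and 0.37. niiA, AO090003000089 and AO090003000091 were chosen after their values were seen.

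**Figure D3:**
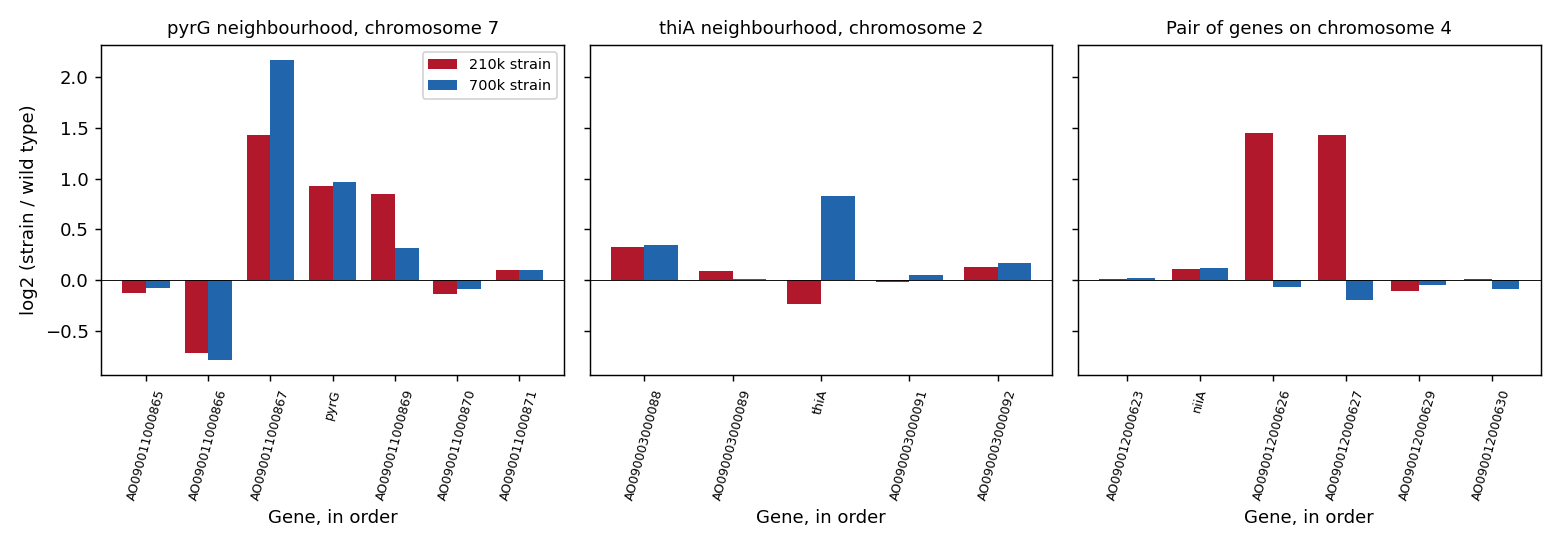
Log2 ratio of strain over wild type (vertical axis, bars from 0) of genes in order around pyrG, thiA and a pair of chromosome 4 genes (horizontal axis) in both strains. pyrG is high in both strains (0.93 and 0.97), thiA only in Ao-700k-dup among these arrays (0.83), and the chromosome 4 pair only in Ao-210k-dup (1.45 and 1.43).

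Of the fixed gene lists, the mitochondrial genome had the highest median on both arrays. Its 22 genes had a median of 1.18 in Ao-210k-dup, with all 22 above 0.5, and 0.42 in Ao-700k-dup, with 9 above 0.5. Both medians were above all 10000 random lists of 22 genes. The 22 genes share the mitochondrial genome and are not independent members, unlike scattered genes of the random lists, so this rank is only a description. With intensity loess the medians were 0.84 and 0.07, with 19 and 0 genes above 0.5, so the higher level in Ao-700k-dup depended on that choice. With the GC trend subtracted they were 1.35 and 0.58, with 22 and 15 genes above 0.5. Of the 6 selection and host-strain loci, pyrG and thiA are given above, and argB, of arginine synthesis, read -0.02 and -0.09, sC, ATP sulfurylase, -0.22 and -0.09, the Ku80 gene -0.05 and -0.15 and the Ku70 gene 0.10 and 0.06, in Ao-210k-dup and Ao-700k-dup. The list's medians were -0.04 and -0.02, at percentiles 35.1 and 40.7. Medians were 0.00 and -0.02 for 11 proteases and peptidases (percentiles 51.0 and 40.6), -0.05 and -0.01 for 28 secondary metabolism genes (12.7 and 39.8), 0.03 and 0.01 for 5 major facilitator transporters (60.6 and 55.2) and 0.18 and 0.16 for 5 cytoplasmic ribosomal protein genes (94.5 and 95.0). The ribosomal medians were 0.20 and 0.004 with intensity loess and 0.315 and 0.277 with normexp. The starch-degrading list matched 1 gene, agdC, at 0.14 and 0.19. No member of the lists lay in either target segment. Lists were matched on symbols, and in the Ao-210k-dup segment only bxlB and abfI had a symbol. The absence of list members therefore does not show that the segments lack genes of these kinds.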

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

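The tests of AO090011000869 were chosen after its values were seen and the other tests of spots and GC content before, and the patterns themselves were noticed in the data. Results of these kinds stood out: genes on opposite sides of 0 on the 2 arrays, and spots without a gene name. thiA read -0.23 in Ao-210k-dup and 0.83 in Ao-700k-dup, and AO090012000627 read 1.43 and -0.19. The values below 0 are about the SD of genes outside the targets (0.21 in Ao-210k-dup and 0.17 in Ao-700k-dup), so each gene shows a gain on 1 array and no clear change on the other. The difference was not tested, since each strain has 1 array, and only named genes outside the target segments with values of at least 0.1 in size on both arrays were considered.

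The gains at pyrG, its neighbours AO090011000867 and, in Ao-210k-dup, AO090011000869, thiA and the chromosome 4 pair were weighed against technical causes. A defect of 1 spot is argued against, since the spots of these probes differed by at most 0.062 (0.004 for AO090011000869), although AO090011000867 in Ao-700k-dup had 1 usable spot. GC content of the probes is argued against too, as the smallest gain was 0.84 after the GC trend was subtracted (0.86 for AO090011000869). Background correction stays open for AO090011000867, which normexp took from 1.43 to 0.30 in Ao-210k-dup, under the threshold of 0.5, and from 2.17 to 0.76 in Ao-700k-dup. Inside the target segments, normexp also took genes as low as 0.11 in Ao-210k-dup and -0.04 in Ao-700k-dup, so such a fall does not decide against a gain. Cross-hybridisation, for which no genome sequence was used here, and introduced DNA, which the labels give for pyrG but not for thiA or the chromosome 4 pair, were not tested.

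Spots without a gene name or sequence showed runs of high values on consecutive probe numbers. Only the longest run per class and array with a running median above 0.5 is given, so its high median partly follows from that rule. The classes held 10949 (Control_B), 5330 (Control_C) and 868 (unnamed AOV2-01) probes. On the Ao-700k-dup array, 204 probes of the Control_B class had a median of 1.02 (0.00 on the other array), 22 of Control_C had 1.01 (0.04) and 13 unnamed AOV2-01 probes had 0.94 (-0.04). On the Ao-210k-dup array, 60 probes of Control_B had a median of 0.94 (-0.01) and 30 of Control_C had 0.91 (0.01).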

How the results depend on the processing

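No paired analysis was possible because each strain has 1 array, and leave-one-out was not possible for the same reason. Both segments kept their boundaries under all 13 alternatives run for length (214 and 698 kb). Leaving out dim probes removed none and the series table's values equalled the processed ones for its features, so neither bears on stability. Leaving out probes with a near-identical match elsewhere was not run, since it needs a genome.

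Normexp raised the segment medians to 1.44 and 1.49, the best windows to 1.45 and 1.49, and the single genes beyond the threshold to 962 and 702, for Ao-210k-dup and Ao-700k-dup. For Ao-700k-dup, loess gave a segment and window median of 0.985 with 34 single genes, and the difference between the arrays a median of 1.002. That difference left 4 segments outside the target, mirrored in both strains by construction, and 75 single genes for Ao-210k-dup. Segments called outside the target in Ao-210k-dup numbered 14 with the hidden Markov model and 2 at a call threshold of 0.5. Single genes numbered 1560 and 1018 at a threshold of 0.3, and 65 and 15 at 0.7. The cause of these shifts was not tested. The remaining 151 values of these results, those settings included, moved by less than their spread or within 1.5 times. Among these, segments called outside the target in Ao-210k-dup numbered 6 both with normexp and at a penalty of 12, against 9. Of 540 values of named genes and lists, 75 moved, and none beyond 0.5 changed sign. Those that moved include 50 of the 111 values with normexp and 17 of the 111 with loess. All probes were well above background, so signal did not limit which genes were measured.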

Other observations

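The test of position beside gaps and the comparison with the other array were chosen after the values were seen, and the other tests before. The chromosome 7 gain of Ao-210k-dup, of 44 genes at a median of 0.64, is not named in the labels. An effect of probes, dye or reference shared by both arrays is argued against, since the same genes had a median of -0.019 in Ao-700k-dup. GC content of the probes is argued against by a median of 0.61 after the GC trend was subtracted. The GC content of the labelled fragments was not measured. The rise seen beside the largest gene-free gap is argued against by the 138 genes that lie between the gain and that gap of the chromosome. Smaller gaps were not tested. Of the 9 gains outside the target, 3, this one included, do not hold the largest gap of their chromosome. A regional rise away from that gap is therefore not covered by this distance. A gain carried by part of the nuclei remains an untested possible explanation for a value below 1.

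Of the 9 gains called outside the target in Ao-210k-dup, 6 hold the largest gene-free gap of their chromosome, on gene order in assembly ASM18445v3. The 40 genes around that gap had medians of 0.27 to 0.42 over the 8 chromosomes in Ao-210k-dup and 0.06 to 0.17 in Ao-700k-dup. On 7 of 8 chromosomes, all but chromosome 2 (88.5% in Ao-700k-dup), they lay above 90% of 40-gene runs of the same chromosome on both arrays, against 0.415 chromosomes expected if gap positions were random. The position was noticed in these calls, and the arrays share their reference and correlate at r = 0.882, so this count restates the pattern and a role of position stays open. The runs compared included the target segments, whose high values lower the percentage for chromosome 2 in Ao-700k-dup and chromosome 8 in Ao-210k-dup. The 0.415 rests on the same runs. Chromosome 2 is thus no clear exception, with a gap median of 0.14 in Ao-700k-dup. GC content of the probes is argued against, since the median over chromosomes in Ao-210k-dup was 0.36 after the GC trend was subtracted. The GC content of the labelled fragments was not measured. Whether the gaps mark centromeres and whether the DNA preparations differed were not tested.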
